A study of Homo sapiens with 4 samples.

How the data were processed

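Messenger RNA was sequenced from cultures of 2 human liver cancer cell lines, LM3 (hepatocellular carcinoma) and RBE (intrahepatic cholangiocarcinoma). Per the labels' protocols, cells of each line were transfected by lipofection with a small interfering RNA against the long noncoding RNA FENDRR (si-FENDRR) or with a negative control (si-NC). RNA was taken after 48 h with Trizol, and libraries were made with an mRNA kit that can be run with or without strand information. The strand setting used is not given in the sources used here. Each line has 1 library per transfection, so the series holds 4 libraries.

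The deposited values are FPKM, fragments scaled to gene length and to mapped fragments, per the file headers. Reads were checked with FastQC and aligned with HISAT2 to the human genome build hg38, per the submitters' processing notes, which give no versions. The program that estimated FPKM, the annotation, its filters and its treatment of reads that fit several genes are not given in the sources used here. The table lists 58174 genes, and its single-library files hold the same values. Of these gene identifiers, 57836 are in GENCODE release 29, where 97.8% of the matched genes have the same start and 97.8% have the same end. Coordinates, gene types and overlaps were taken from that release, which is on GRCh38. A gene was called overlapping when an exon of it shared bases with an exon of another listed gene on the same strand.

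The files carry no read counts. In single-exon genes, low values multiplied by gene length piled up at 1 step per library, between 43.0 and 49.9 FPKM times base pairs. Read as the worth of 1 fragment, this step would correspond to a depth of 20.1 to 23.3 fragments per library, in units of 1e6. Only 13.0% to 20.3% of the low values lay within 0.02 of a whole multiple, so reads were not recovered and no counting interval or detection floor is given. FPKM values of 0 can be failed estimates, and such genes are described as listed at 0.

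The design had set a count-based test for whole reads, and for other units limma on log2 values. The FPKM therefore went into limma version 3.58.1 in R version 4.3.3, as log2(FPKM + 1) with a trended prior variance, over 15930 genes with an FPKM of at least 1 in any library. The model had a term for cell line and a term for transfection, so the lines served as the replicates and 1 residual degree of freedom was left. P-values of the transfection term measure how alike the 2 lines responded. Those of the line term measure how alike the difference between the lines was with si-FENDRR and with si-NC. The labels name no independent culture within a line. The Benjamini-Hochberg threshold was 0.05. All fold changes are on the log2(FPKM + 1) scale, which understates changes of weakly expressed genes. Errors beside log2 changes are the standard errors of limma. Within a line, no test is possible with 1 library per transfection, and genes were counted when FPKM + 1 differed at least 2-fold. No scaling between libraries was applied beyond that in the FPKM.

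Gene lists were tested with camera in limma at a preset correlation between genes of 0.01. Of 34 lists, 33 had at least 5 measured members. In each line, the median change of a list was placed among 10000 random lists of the same size matched on mean expression in 50 bins. The groups, tests, lists, most alternatives and the rule for naming genes were fixed before the data were examined. The rule took the target and its neighbour FOXF1, the 10 genes per direction with the largest change shared by both lines (past the threshold, filled up with genes not past it), the 10 highest and lowest genes in each line, 2 highest and 2 lowest members of each list, 10 genes per direction between the lines with up to 6 abundant members of each marker list, and 5 genes per direction with opposite changes. Where there were no counts, the point change replaced the bound of a counting interval. Genes named outside the rule are marked as chosen after their values were seen.

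The test was checked on data simulated from the fitted variances over 15930 genes. Of 200 genes changed 2-fold over both lines, 0 were called at the threshold. Of 200 changed 4-fold, 187 were called with 14 unchanged genes, and of 200 changed 16-fold, 193 were called with 8 unchanged genes. Calls with fewer than 200 changed genes, which face a stricter cutoff under Benjamini-Hochberg, were not checked. A list of 30 genes shifted by 0.3 on the log2 scale was called in 20 of 20 simulated data sets, with 2 calls among 640 unshifted lists. The simulated genes varied independently of each other, so false calls in lists whose members move together were not checked. Alternatives covered the scaling of libraries, the pseudocount, the filter on low values, the cell line term and the correlation assumed within lists. Restriction to protein-coding genes without overlap, single libraries left out and a 1.5-fold rule were added after the data were seen. Alternatives set for whole reads, which were count models, read minimums and counting intervals, were not run because the values are not counts. Figures were drawn with matplotlib version 3.10.9 in Python version 3.11.15.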

Results

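The data were transcript levels of LM3 and RBE cells, a hepatocellular carcinoma line and an intrahepatic cholangiocarcinoma line, 48 h after transfection with si-FENDRR or si-NC. FENDRR is a long noncoding RNA transcribed divergently from the transcription factor gene FOXF1. The series asks how FENDRR affects gene expression in primary liver cancer. Each line had 1 library per transfection, with 13437 to 13682 genes at an FPKM of at least 1. The 2 libraries of a line were alike across genes, with Pearson r of log2 values of 0.982 in LM3 and 0.985 in RBE, and libraries of different lines had r of 0.784 to 0.786. Genes are not independent replicates, so these values describe the libraries only. Values within a line have no replicate check.

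The targeted RNA could not be used to check the knockdown. FENDRR (ENSG00000268388, a lincRNA at chromosome 16, 86474529 to 86509099 on the minus strand of hg38, with no exon shared with another listed gene on its strand) was listed at 0 in all 4 libraries, the si-NC libraries included. Its neighbour FOXF1 (chromosome 16, 86510527 to 86515418, plus strand) was listed at 0 in all 4 as well, and so was the nearby forkhead gene FOXC2. The forkhead gene FOXL1 of the same region was at 3.07 FPKM with si-FENDRR and 4.02 FPKM with si-NC in LM3, and at 0 and 0.087 in RBE. MTHFSD, between FOXF1 and FOXC2, was at 6.28 and 7.93 FPKM in LM3 and at 8.82 and 9.22 FPKM in RBE. IRF8 and GSE1 of the same region were higher with si-FENDRR in RBE, IRF8 at 5.08 against 3.60 FPKM and a listed 0 in both LM3 libraries, and GSE1 at 8.25 against 5.50 in RBE and 4.51 against 7.07 in LM3. The list of this region was not called by camera (adjusted p = 0.748), with 3 of 6 measured members lower in both lines and 0 higher in both. The libraries labelled si-FENDRR are therefore compared by label alone.

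Over both lines, no gene was called between si-FENDRR and si-NC at an adjusted p of 0.05 by limma. The smallest adjusted p was 0.473, and 657 genes had an unadjusted p under 0.05 where chance gives 797 of 15930. Genes with the largest shared difference included TGOLN2, a membrane protein of the trans-Golgi network, with 46.1 FPKM under si-FENDRR and 9.06 under si-NC in LM3, and 37.4 and 5.09 in RBE (log2 difference 2.44 ± 0.16 SE, n = 2 lines, adjusted p = 0.473). TGIF2, a homeobox repressor of TGF-beta signalling, was at 5.79 against 1.04 FPKM in LM3 and 12.5 against 2.68 in RBE. SCO2, which helps to assemble cytochrome c oxidase, was at 17.2 against 4.95 and 17.4 against 4.12 FPKM, and the mitochondrial ribosomal protein gene MRPL30 was at 18 against 7.62 and 19.9 against 6.95. None of these passed the threshold. TGIF2, SCO2 and MRPL30 have exons that overlap another gene, so reads may have been split between models.

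In the other direction, GSPT1, the translation termination factor eRF3a, was at 22.8 FPKM with si-FENDRR against 65.5 with si-NC in LM3, and at 39.3 against 129 in RBE (log2 difference -1.58 ± 0.12 SE, adjusted p = 0.533 by limma). The actin-severing protein gene CFL2 was at 9.34 against 30.9 FPKM in LM3 and 5.54 against 32.5 in RBE. SPATA2, an adaptor of the deubiquitinase CYLD, was at 2.14 against 9.73 and 1.64 against 5.61 FPKM, and MAPK14, the stress kinase p38 alpha, at 5.44 against 13.7 and 5.96 against 18. None passed the threshold, and none of these 4 genes shares exons with a gene on its strand. The rest of the 20 genes with the largest shared difference were small RNAs, readthrough or overlapping models, namely AP000275.2, INO80B-WBP1, AL645465.1, SNORA61, MIR4458HG and ZNF321P among the higher, and AC004922.1, MIR6506, AC245033.1, SNORD88C, TMEM189-UBE2V1 and COMMD3-BMI1 among the lower. AC004922.1, a model that overlaps other genes on chromosome 7, was at 5.79 FPKM against 163 in LM3 and 2.78 against 38.9 in RBE.

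**Figure D1:**
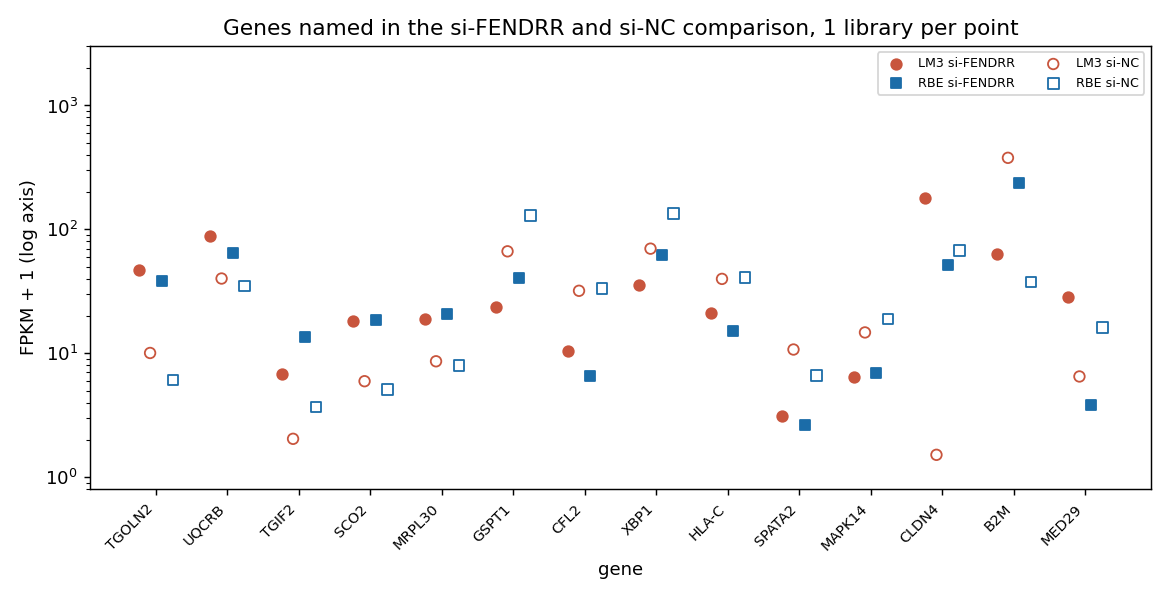
FPKM + 1 on a log axis of 14 genes of the transfection comparison, 1 point per library (circles LM3, squares RBE, filled si-FENDRR, open si-NC; no error bars, since each point is 1 library). TGOLN2 is higher with si-FENDRR in both lines (46.1 against 9.06 FPKM in LM3), GSPT1 is lower in both (22.8 against 65.5 in LM3), and B2M goes opposite ways.

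Among the 33 gene lists, 1 rose and 1 fell over both lines by camera. Neither call held when the correlation within lists was estimated, or when the cell line term was left out, which counts the difference between the lines as error. With an estimated correlation camera rests on the 1 residual degree of freedom, and the smallest adjusted p of any list was 0.978. A call lost there does not show that correlation among members had made it. For immediate-early genes the estimated correlation was -0.02, under the preset 0.01. For genes of hypoxia and glycolysis, the list that fell, it was 0.05, above the preset, so that list's adjusted p by camera may be too small. Immediate-early genes, the transcription factors and feedback regulators induced within minutes by growth factors, rose as a list (adjusted p = 0.0304). Of 31 measured members, 15 (48.4%) were higher with si-FENDRR in both lines and 3 lower in both. Of all tested genes, 26.9% were higher in both and 21.8% lower in both. The median log2 difference of the list was 0.08 in LM3 and 0.17 in RBE, at percentiles 97.6 and 99.97 of random lists. In LM3 and RBE it was 0.04 and 0.20 with library totals as the scaling, and 0.04 and 0.14 with median-of-ratios scaling. IER2 was at 54.8 FPKM against 23.9 in LM3 and 13.8 against 11.4 in RBE, and EGR1 at 158 against 135 and 10.6 against 4.28. FOSL2 was lower with si-FENDRR in both lines, at 7.31 against 9.30 and 2.20 against 9.84 FPKM, and ZFP36 went opposite ways. No member passed the threshold over all genes or adjusted over the list alone (smallest adjusted p 0.226). The list had an adjusted p = 0.978 with an estimated correlation and an adjusted p = 0.198 without the cell line term.

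Genes of hypoxia and glycolysis fell as a list (adjusted p = 0.0414 by camera), with 12 of 31 members lower in both lines and 3 higher in both (21.8% and 26.9% of all tested genes). The median log2 difference was -0.06 in LM3 and -0.03 in RBE, at percentiles 13.1 and 9.37, and with library totals as the scaling the RBE median was 0.01. The hexokinase HK1 was at 25 FPKM with si-FENDRR against 41.7 in LM3 and 18 against 25.9 in RBE, and the hypoxia-induced demethylase KDM3A at 12.6 in both LM3 libraries and 6.59 against 11.7 in RBE. PDK1, which limits pyruvate oxidation, was at 9.12 against 4.78 FPKM in LM3 and 0.979 against 1.30 in RBE. The list had an adjusted p = 0.978 with an estimated correlation, 0.159 without the cell line term and 0.0889 with no filter on low values, and no member passed over all genes or adjusted over the list alone.

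S-phase genes did not pass the threshold (adjusted p = 0.0536 by camera, and 0.978 with an estimated correlation). They had median log2 differences of 0.11 in both lines, with 14 of 30 members higher in both and 2 lower in both (26.9% and 21.8% of all tested genes). The medians in LM3 and RBE were 0.07 and 0.14 with library totals as the scaling, and 0.07 and 0.08 with median-of-ratios scaling. PCNA, the sliding clamp of DNA replication, was at 101 FPKM with si-FENDRR against 80.4 in LM3 and at 106 against 82.4 in RBE, and the cyclin gene CCNE2 at 3.18 against 1.80 and 1.39 against 0.999. Genes of the G2 and M phases had medians of 0.01 and 0.06 (adjusted p = 0.748). The other lists had adjusted p-values from 0.305, for YAP targets, to 0.976. Lists of interferon response, p53 targets, apoptosis regulators, epithelial junctions, mesenchymal genes and genes linked to FENDRR in earlier publications were among these. The FENDRR list was written from memory. For epithelial junctions the mean log2 difference over both lines was 0.13 and the median -0.03, since CLDN4 alone reached 3.25.

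Adjusted over the list alone, 2 single members passed by limma, though neither passed over all genes. This adjustment was made separately in each of 33 lists, so some list can hold a passing member by chance. XBP1, the transcription factor of the unfolded protein response, was at 34.4 FPKM with si-FENDRR against 68.9 in LM3 and at 60.8 against 133 in RBE (log2 difference -1.05 ± 0.11 SE, adjusted p = 0.0179 over the list alone and 0.783 over all genes). UQCRB, a subunit of respiratory complex III, was at 86.7 against 39.1 FPKM in LM3 and 63.1 against 33.8 in RBE (1.01 ± 0.12 SE, adjusted p = 0.0477 over the list alone and 0.948 over all genes). The other measured members of these lists did not pass, and neither list was called (adjusted p = 0.748 for both). In the list of antigen presentation and immune evasion, HLA-C, a heavy chain of MHC class I that shares sequence with its paralogs, was at 20.3 against 38.9 FPKM in LM3 and 14.3 against 39.7 in RBE (-1.16 ± 0.17 SE, adjusted p = 0.959 over all genes). No member of that list passed over the list alone, where the smallest adjusted p was 0.0581.

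**Figure D2:**
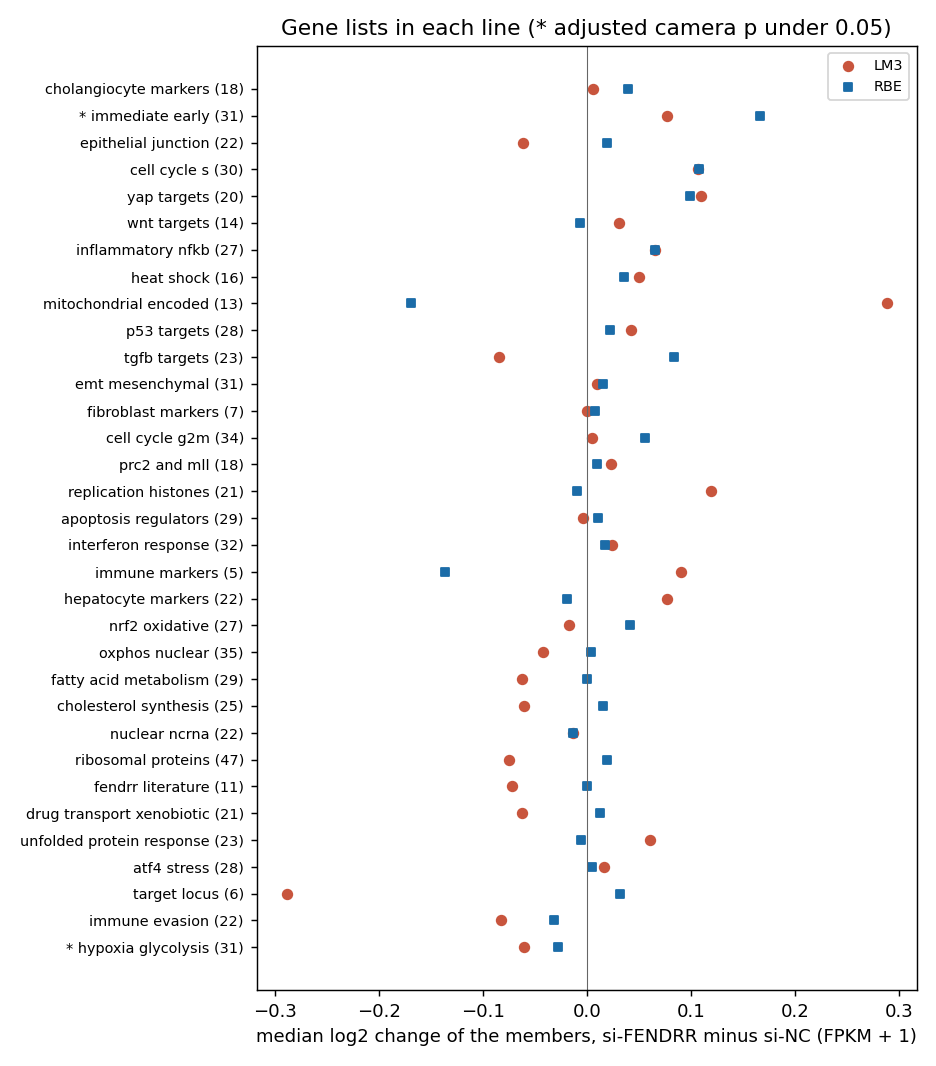
Median log2 difference of FPKM + 1 between si-FENDRR and si-NC for each of 33 gene lists, with the number of measured members in parentheses (circles LM3, squares RBE, 1 pair of libraries per point, so no error bar). Asterisks mark the lists past the threshold by camera at the preset correlation. Immediate-early genes lie at 0.08 and 0.17, and mitochondrially encoded genes at 0.29 in LM3 and -0.17 in RBE.

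Within LM3, 339 genes (2.13%) differed at least 2-fold between the 2 libraries, 189 higher and 150 lower with si-FENDRR. The largest difference was in CLDN4, a tight junction claudin, at 179 FPKM against 0.515. The readthrough model BLOC1S5-TXNDC5 was at 38.3 FPKM against a listed 0, AL121758.1 at 12.8 against 0.00785 and AL662899.3 at 19.9 against 0.856. The most reduced were AC004922.1, the readthrough MINOS1-NBL1 (0.195 against 15.8 FPKM), the pseudogene AC211486.4 (0.128 against 11.3) and the microRNA gene MIR22 (0.104 against 11), followed by AC020915.6, UBE2F-SCLY, AC007731.5 and the small nucleolar RNAs SNORD65, SNORD22 and SNORA17. Of the annotated genes among the 339, 39.3% overlap another gene on their strand, against 16.9% of all tested genes, and 56 are small RNAs. Among all 15930 tested genes, 372 are small RNAs. The libraries were made with an mRNA kit, and mature small RNAs were not measured separately.

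Within RBE, 279 genes (1.75%) differed at least 2-fold, 140 higher and 139 lower with si-FENDRR. Among the highest were AC093525.2 (23.5 FPKM against 0.342), INO80B-WBP1 (13.7 against a listed 0) and AP002990.1 (89.2 against 8.73), with B2M, the light chain of MHC class I, at 238 against 36.5. Among the lowest were the pseudogene AP005202.1 (1.33 against 74.1), RPL36A-HNRNPH2 (0.682 against 50.3), AC096677.3 (0.421 against 40.7) and HNRNPH2 (4.22 against 32.0), a ribonucleoprotein that shares exons with RPL36A-HNRNPH2. Of the annotated genes among the 279, 41.0% overlap another gene on their strand, and 39 are small RNAs. In each line, counts of this kind compare 2 libraries and not the transfections.

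The changes of the 2 lines were not related across genes, with Pearson r of 0.01, Spearman rho of 0.02 and the same sign in 50.9% of the genes whose values differed between the libraries of each line. At least 2-fold changes in the same direction in both lines were seen in 24 genes where independent lists would share 2.97, and changes in opposite directions in 25 genes where independent lists would share 2.97. These counts depend on the pseudocount, with 98 and 103 genes at 0.1 and 8 and 10 at 5. B2M was at 62.6 FPKM with si-FENDRR against 377 in LM3, the reverse of its difference in RBE. MED29, a Mediator subunit, was at 27.7 against 5.50 FPKM in LM3 and 2.79 against 15.1 in RBE. ZBED6 and ZC3H11A, which share exons, moved apart within each line: ZBED6 was at 13.2 against 0.718 FPKM in LM3 and 1.18 against 13.6 in RBE, while ZC3H11A was at 3.11 against 16.4 and 11 against 2.60.

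**Figure D3:**
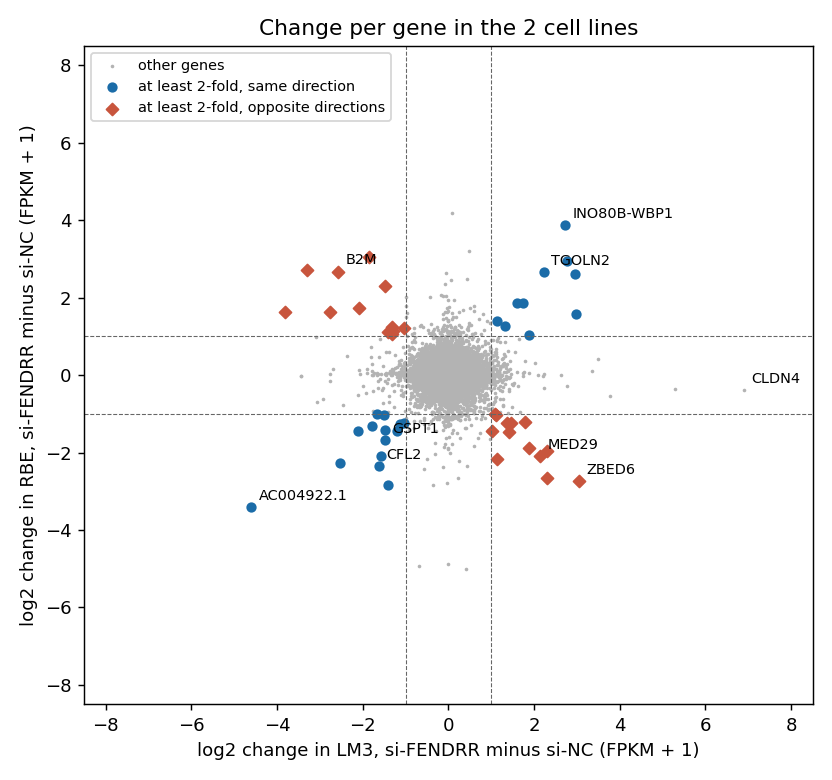
Log2 difference of FPKM + 1 between si-FENDRR and si-NC per gene, LM3 on the horizontal axis and RBE on the vertical axis, with dashed lines at 2-fold (1 library per transfection and line, so no error bars). The 24 genes changed in the same direction in both lines (circles) stand beside 25 changed in opposite directions (diamonds), and Pearson r over 15930 genes is 0.01.

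The lines themselves differed far more than the transfections. Of the 15930 genes, 9348 (58.7%) were called between LM3 and RBE by limma, 5147 higher in LM3 and 4201 higher in RBE. The 2 libraries of a line differ in transfection, so these calls rest on no replicate culture of 1 condition. The split depends on the scaling: with median-of-ratios scaling 50.1% of 9417 called genes were higher in LM3, against 55.1% here. LM3 carried the hepatocyte secretory genes ALB, at 35.7 and 33.3 FPKM against 0.251 and 0.270 in RBE, and AFP, at 10.1 and 8.25 against a listed 0, together with the liver transcription factor gene CEBPA at 81.8 and 93.1 against 2.89 and 2.69 (4.54 ± 0.13 SE, n = 2 libraries per line, adjusted p = 0.00065). RBE carried biliary genes, with the keratin KRT7 at 429 and 391 FPKM against 7.21 and 6.02 in LM3, and the surface antigen CD24 at 95 and 112 against 0.473 and 0.468. ALB and AFP were chosen after their values were seen. The cholangiocyte list was higher in RBE (adjusted p = 0.00226 by camera, 11 of 18 members called higher in RBE and 2 in LM3), a call that was lost at an adjusted p = 0.653 with an estimated correlation. The hepatocyte list was not called (adjusted p = 0.857, 9 of 22 members higher in each line), and SERPINA1 and AMBP of that list were higher in RBE, SERPINA1 at 56.8 and 82.5 FPKM against 0.0957 and 0.0892. Not all biliary markers were higher in RBE: SPP1 was at 1118 and 909 FPKM in LM3 and 515 and 504 in RBE.

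**Figure D4:**
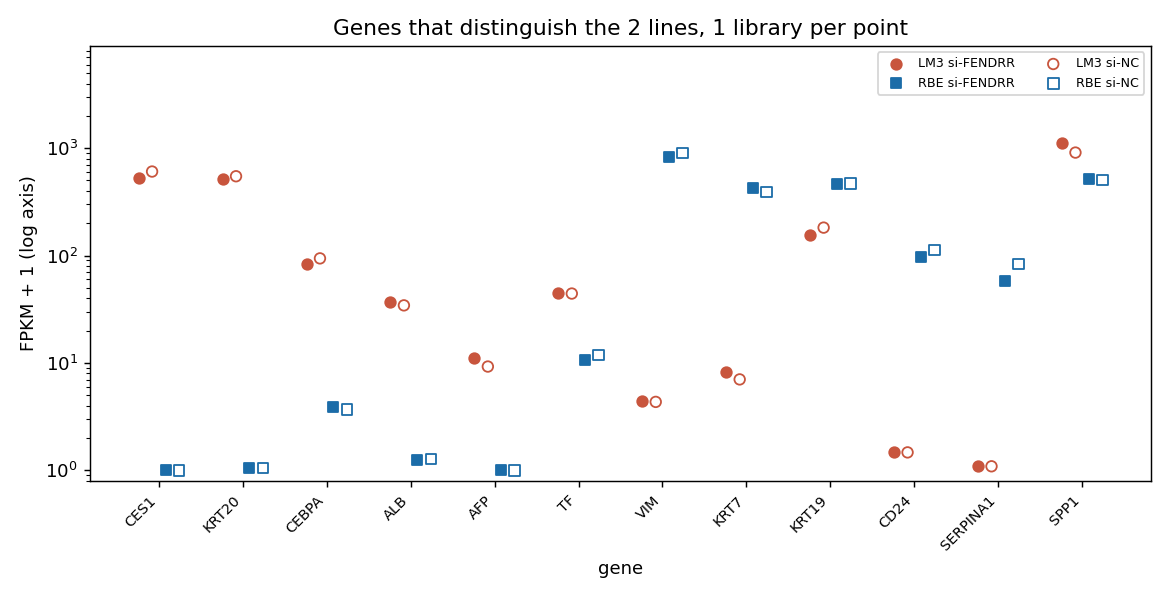
FPKM + 1 on a log axis of 12 genes in the 4 libraries (circles LM3, squares RBE, filled si-FENDRR, open si-NC; 1 library per point, no error bars). ALB, AFP and CEBPA are higher in both LM3 libraries, and KRT7 and CD24 in both RBE libraries (KRT7 at 429 and 391 FPKM against 7.21 and 6.02).

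The largest differences toward LM3 were in the carboxylesterase CES1 (522 and 605 FPKM against a listed 0), the keratin KRT20 (520 and 546 against 0.0494 and 0.0493), S100P, UCHL1, the galectin LGALS4, AC079466.1, ABCA4, SPANXA1, MSC and the lactate dehydrogenase subunit LDHB (498 and 458 against 2.25 and 3.22). Those toward RBE were in FXYD2 (430 and 410 FPKM against a listed 0), the intermediate filament VIM (820 and 897 against 3.45 and 3.33), COTL1, YBX3, CLDN2, ALDH1A3, PMEPA1, SERPINA6, ACTA2 and CD24. FXYD2 and ALDH1A3 share exons with another gene. Their log2 differences ran from 6.15 to 9.14 in size, all with an adjusted p of 0.000584 by limma. Ribosomal protein genes were lower in LM3, with 43 of 47 called (adjusted p = 1.28e-11 by camera), and NRF2 targets of the oxidative stress response were higher in LM3, with 21 of 27 called (2.88e-06). Both calls were lost, at an adjusted p = 0.666 for ribosomal proteins and 0.653 for NRF2 targets with an estimated correlation. Targets of YAP (17 of 20 called), p53 targets (17 of 28), nuclear genes of oxidative phosphorylation (21 of 35), cholesterol synthesis (15 of 25) and epithelial junctions (15 of 22) were higher in RBE at the preset correlation, each with an adjusted p = 0.653 with an estimated correlation. Genes of the G2 and M phases (24 of 34), inflammatory genes (19 of 27), interferon response (20 of 32), drug transport and metabolism (13 of 21) and replication histones (11 of 21) were higher in LM3 at the preset correlation, each again with an adjusted p = 0.653 with an estimated correlation. No list passed between the lines under that setting, which rests on 1 residual degree of freedom. These losses, that of the cholangiocyte list included, therefore do not by themselves show that correlation among members made the calls. The estimated correlation was 0.42 for ribosomal proteins and 0.20 for NRF2 targets, above the preset 0.01, so their adjusted p-values by camera may be too small. It was 0.09 for epithelial junctions, 0.04 for cholesterol synthesis and 0.012 for oxidative phosphorylation. In the other called lists it ran from -0.06 (cholangiocyte) to 0.002 (G2 and M phases).

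Markers of other cell types were low in the libraries. The median FPKM of fibroblast, endothelial and immune markers was at most 0.164 in any library, with 7 of 16, 2 of 14 and 5 of 19 genes reaching an FPKM of 1 in any library. Of these, ACTA2 was at 108 and 111 FPKM in RBE and the B-cell receptor gene CD79A at 16.8 and 19.2 in LM3. None of the fibroblast and immune lists was called between transfections (adjusted p = 0.976 for both).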

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

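Some named genes were listed because their 2 libraries differed at least 2-fold in each line, in opposite directions, and 1 list because its median lay at percentile 99.98 of random lists in LM3 and at 0.29 in RBE. With 1 library per line and transfection these differences between the lines were not tested. The tests of genes changed in both lines and of FENDRR were chosen after the result was seen, and those of the intestinal list before its members were looked up.

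The log2 change in LM3 minus that in RBE was 5.79 for ZBED6, 4.97 for FP565260.2, 4.23 for MED29, 4.27 for SNORD116-4 and 3.77 for SNORD5. It was -6.02 for AC020915.6, -5.44 for MINOS1-NBL1, -5.24 for B2M, -4.90 for AC010323.1 and -3.82 for ZC3H11A. The mitochondrially encoded mRNAs had a median log2 change of 0.29 in LM3, with 13 of 13 higher with si-FENDRR, and of -0.17 in RBE, with 1 of 13 higher, a difference of 0.46. Their share of the summed FPKM was 17.6% with si-FENDRR and 15.1% with si-NC in LM3, and 16.6% and 18.3% in RBE. These mRNAs moved together in each line, which genes drawn into random lists need not do. The percentiles among random lists therefore do not measure how unusual such a shift is.

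The pattern behind these genes is that 49 genes changed at least 2-fold in both lines, and 51.0% of them in opposite directions, at a pseudocount of 1. A response shared by the lines as the whole cause is argued against by the 49.0% that changed in the same direction (exact 95% interval 34.4% to 63.7%). The interval treats genes as independent, which models that share exons, such as ZBED6 and ZC3H11A, are not. Of the 16 genes that overlap no listed exon on either strand, 6 changed in the same direction and 10 in opposite directions. Low expression and protein-coding status are argued against as the whole cause. RBE changes permuted among genes of like expression, same-strand overlap and protein-coding status gave a mean of 11.5 and at most 21 shared genes. Small RNAs, 56 of the genes changed in LM3 and 39 of those in RBE, were not matched as a class of their own. Shared exons as the whole cause are argued against by 16 of the 49 that overlap no listed exon on either strand, B2M, RALB, VAPA and TGFBR2 among them (named after their values were seen). What stays open is that estimates of some genes swing from library to library, or that the lines respond in opposite ways, and with 1 library each these cannot be told apart; where exons are shared, the most abundant partner moved the other way for 64.8% of the changed genes in LM3 and 63.0% in RBE, against 50.5% and 54.0% for unchanged genes, which may reflect reads moved between models but lies within the error in RBE.

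FENDRR was listed at 0 in all 4 libraries. Expression too low to be seen may account for it, since 58.4% of the 7315 lincRNA genes were listed at 0 in all 4. A failed estimate is also open: 6 genes were listed at 0 in 1 library and at an FPKM of at least 5 in the other library of the line, but all 6 share exons with another gene and 0 genes without overlap did so, and a failure common to all 4 libraries would not be seen this way. Of 91 ribosomal protein, oxidative phosphorylation and mitochondrial genes, 0 were listed at 0 in any library. The files do not decide whether si-FENDRR lowered FENDRR.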

How the results depend on the processing

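Over both lines 0 genes were called by limma under every scaling, pseudocount, filter and gene set tried. Without the cell line term, with all libraries or any 1 left out, 0 were called too (28 to 32 at an unadjusted p under 0.05, against 657 with the term), but the difference between the lines is then counted as error, so these fits do not test the transfection. A whole line left out leaves no test, only the 279 genes changed in RBE or the 339 in LM3. The counts of 2-fold changes depend on the pseudocount and the gene set: with a pseudocount of 0.1 they were 940 in LM3 and 818 in RBE, with 5 they were 100 and 83, and with protein-coding genes without overlap (fewer genes tested) 130 and 125. Genes changed in both lines in the same and in opposite directions, 24 and 25, were 98 and 103 with a pseudocount of 0.1, 8 and 10 with 5, and 8 and 11 without overlap. An FPKM of at least 5 left 217 in LM3, and a 1.5-fold rule gave 1269 and 999. The correlation of the lines stayed between -0.00309 and 0.0222. Of the 2 called lists, 0 were called with an estimated correlation, a setting that rests on 1 residual degree of freedom and passed no list in either comparison. With no replicate block 0 were called too, where the difference between the lines is again counted as error. Immediate-early genes passed under each scaling, pseudocount, filter and gene set (adjusted p 0.00607 to 0.0343). The restriction to genes without overlap (0.00607) was chosen after the call was seen, and the estimated correlation (adjusted p = 0.978) before. Hypoxia and glycolysis passed under these too, except with no filter (0.0889; range 0.0184 to 0.0889). S-phase genes passed with a pseudocount of 5 (0.0465), with no filter (0.0308) and without overlapping genes (0.0332). Their medians without one line are those of the other line. Between the lines, 50.1% to 56.8% of the called genes were higher in LM3 under the scalings, 6444 to 9643 genes were called, and 5573 to 6980 with any 1 library left out, fewest without the RBE si-NC library (5573) and the RBE si-FENDRR library (5836), where RBE is assumed to vary like LM3. Of 179 named genes of the transfection comparison, 5 took another sign under a scaling or pseudocount (AC010323.1, COL3A1, LAPTM5, MED29 and SNORD5), none of them called, and of 32 between the lines, 0 did. The cause of these changes was not tested. FENDRR gave no value. Alternatives for read counts (count models, read minimums, counting intervals) were not run. Without counts the precision of a single library is unknown, and a 2-fold change shared by both lines was not detectable at the threshold (0 of 200 simulated). Larger shared changes were called in simulated data only with 200 genes changed at once. In the data, AC004922.1 had a log2 change of -4.00 over both lines and an adjusted p = 0.542 by limma. The 0 calls therefore do not exclude shared changes larger than 2-fold.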

Other observations

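The LM3 libraries carried several genes of intestinal epithelium. KRT20 and LGALS4 had stood out between the lines, at 520 and 546 FPKM and at 329 and 372 FPKM in LM3, and a list of 22 intestinal genes was then written, with the tests fixed before its other members were looked up. S100P had also been seen and is not in the list, and TFF3 had been in the cholangiocyte list. Leaving KRT20 and LGALS4 out, 20 remain, of which 8 reached an FPKM of 1 in any library (TFF3 did not), and 7 were called higher in LM3 than in RBE by limma, with a median log2 difference of 2.05. CDH17, a cadherin of the intestine, was at 46.6 and 53.1 FPKM in LM3 against 3.78 and 4.25 in RBE, CEACAM6 at 88.9 and 76.1 against 1.08 and 0.823, MUC13 at 37.7 and 35.0 against 2.26 and 3.02, and the microvillus protein gene VIL1 at 36.6 and 29.5 against 7.58 and 7.35. The intestinal transcription factor gene CDX2 was at 2.24 and 2.65 against 0 and 0.0224. CDX1, GPA33 and FABP1 were listed at 0 in both LM3 libraries, CEACAM5 was at 0.0220 and 0.0281, and VIM at 3.45 and 3.33.

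A candidate explanation is an intestinal-type expression program in the LM3 libraries, for which 7 of the 8 tested members (87.5%), against 32.3% of all tested genes, were called higher in LM3. CDX2 and CDHR5 passed the filter only through LM3, so this share depends on the filter. It also leaves out the listed members under an FPKM of 1 in every library, MUC2, GUCY2C, REG4 and ATOH1 among them. An admixture of other cells that varies between cultures stays open. The median difference between the LM3 libraries was 0.13, at percentile 90.4 of random lists. This met the bound set beforehand against such an admixture, a median inside the random lists and small in size. But 6 of the 8 tested members were higher and 2 lower with si-FENDRR in 1 pair of libraries, so the bound alone does not decide it. An admixture equal in both cultures, the line's own expression and a culture other than its label were not tested, since no reference profile of either line was used here. VIL1, MUC13, HNF4G and CDH17 are also expressed in biliary or hepatic tumours, so the list does not name an origin.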
